A study of Rattus norvegicus with 11 samples.

How the data were processed

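Total RNA of islets, 100 ng per sample, was labelled with Cy3 and hybridised to 1-colour Agilent miRNA arrays, per the labels' protocols. The deposited files hold 1 array each, as the scanner software Agilent Feature Extraction wrote them. Per the file headers the software was version 10.5.1.1 for the 8 arrays of the first design and 10.7.3.1 for the 3 arrays of the second. The deposited spot intensity is already background-subtracted and spatially detrended within the array and is not normalised between arrays, per the file headers. A second deposited file per array holds the software's total intensity per miRNA and whether that miRNA was detected. The authors also deposited 2 tables of log2 values, 1 per design, whose scale was found by setting each column against that array's own file. The first table, of 340 miRNAs, equals log2 of the total intensity plus 50, with no scaling between arrays. The second, of 677, equals log2 of the total intensity where detected and is blank elsewhere, except in 7 cells. Column medians were 5.70, 5.70, 5.68 and 5.69 for Control 602, 613, 615 and 639, 5.69, 5.73, 5.71 and 5.83 for HFD 603, 607, 644 and 653, 6.59 and 6.89 for Control 635 and 652, and 6.52 for HFD 640. Neither table is centred per miRNA and neither holds ratios, so scale and centring are known and no direction is involved. RMA and Partek are named in the submitters' processing notes, with their role and version not given in the sources used here.

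Array design, slide and scan coincided, and both slides held both groups, so array design was the block in every main test. miRNAs were matched between designs by name, since the files give no accession. Of 340 shared names, 314 have the same probes on both designs and 26 share no probe. Of the latter, 4 were tested and 3 are named in the text, miR-200c, miR-383 and miR-487b. The block takes up a difference in level between probes, and whether those names stand for the same sequence on both designs is not known from the files. 10 names of the first design and 337 of the second were on 1 design only. No array pair held identical values. Correlations between arrays over tested miRNAs, which are not independent replicates, ran from 0.917 to 0.993 on the first design.

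In the main setting, the mean processed signal over spots without an outlier flag was taken per probe (over all spots where each had a flag), probes were summed per miRNA, and each array was scaled by its 75th percentile over the 85 miRNAs detected on all 11 arrays. Values under the 1st percentile of scaled detected values, 11.3, were set to that floor, and log2 was taken. The floor can shrink the difference of a dim miRNA or turn its sign, as for miR-146a, which read -0.082, or 0.089 with the floor at the 5th percentile. Of 46 named and tested miRNAs, 8 had probes of opposite sign on the first design, namely miR-7a, miR-126, let-7c, miR-15b, miR-429, miR-29a, miR-29b and miR-30a. For miR-325-5p and miR-93 no probe read higher on that design although the difference there was above 0. The scaling held miR-26b constant on the first design. On the second design it set let-7i on Control 635 and HFD 640, and let-7d on Control 652, to that same value. No tested miRNA lacked detection throughout 1 group. No spot was saturated.

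Differences are HFD minus Control, from limma 3.58.1 in R 4.3.3 with array design as a block, tested 2-sided with Benjamini-Hochberg adjustment at 0.05 over miRNAs detected on at least 5 arrays. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, with fry, and with exact permutation of the labels within array design (210 splits). Camera compares a list with the other miRNAs, while fry tests whether its members move one way. Relations between measures were computed over 8 arrays with exact permutation over all 40320 orders, and again centred by slide row with the 576 orders within rows, which was chosen after the data were seen. The fit was tested on simulated data for this comparison of 152 miRNAs. With 30 changed miRNAs it recovered 40.5% of log2 changes of 0.5, 74.0% of 1 and 97.5% of 2, with 4.93% false calls. The simulated noise was normal and independent between miRNAs, with no floor. These shares may therefore not hold for dim miRNAs or for fewer changed ones. At an unadjusted p of 0.05, camera called 0 of 20 simulated unshifted lists of 20 miRNAs and 20 of 20 shifted by 0.25, with independent miRNAs. The real lists were called at an adjusted p, and many held fewer than 20 tested members, so these counts do not carry over to them. The number of arrays limits the precision, and p-values treat the samples as independent.

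The lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. Named miRNAs were the 15 of smallest p with any further past the threshold up to 25, 15 anchors whatever their result, and the 2 members of smallest p per list. The anchor miR-148a was not among the shared names. miR-21, miR-142-3p, miR-142-5p and the miRNAs of the second design alone were named after their values were seen. Of 18 lists, 15 had at least 2 tested members. They were islet endocrine-enriched, endothelial, red blood cell, leukocyte, fibroblast and smooth muscle, neuronal, let-7, miR-200, miR-29, miR-30, miR-17-92, the miR-23, miR-24 and miR-27 clusters, Dlk1-Meg3, diabetic or glucose-exposed islet, and beta-cell stress and hypoxia. The exocrine, muscle and liver lists had fewer. Gene neighbours come from the GRCr8 gene table, in which 20 of 20 Dlk1-Meg3 members were matched by name.

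The alternatives were other scalings (75th percentile over all shared miRNAs, median, quantile within design, none), normexp background correction, the software's total signal, the median over probes, an RMA-like summary, the deposited tables, no detection filter or detection on all arrays, the first design alone, no block, limma with trend and robust variance, array weights, outlier spots kept, a floor at the 5th percentile, and each array left out. The mean spot signal that normexp was planned on is not a column of these files, so normexp (offset 50) used the median spot signal and median local background. Deposited values of undetected miRNAs are blank in the second table, and lists there used miRNAs with all values.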

Results

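The arrays measured miRNAs, short RNAs that lower the output of their target mRNAs, in pancreatic islets of female Sprague Dawley rats. Islets are the clusters of hormone-secreting cells of the pancreas, mostly insulin-producing beta cells. The daughters differed in what their fathers had eaten before mating, which took place when the fathers were 15 weeks old. HFD fathers ate pellets with 43% fat and Control fathers ate chow with 9% fat. The daughters were weaned at 3 weeks, underwent glucose tolerance tests at 6 and 12 weeks and an insulin tolerance test at 11 weeks, and gave their islets at 13 weeks. The series thus asks whether a father's diet is accompanied by different miRNA levels in his daughters' islets. There were 11 arrays, 6 Control and 5 HFD, each from a sample numbered separately in the labels, and the labels used here do not say which daughters shared a father or litter. A first array design, with 350 miRNAs, held 4 Control and 4 HFD arrays, and a second, with 677, held 2 Control and 1 HFD array. Their 340 shared miRNA names were compared, and 152 of them, detected on at least 5 arrays, were tested.

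Detection and brightness did not differ detectably between the 2 groups. Control arrays of the first design detected 144 ± 6.75 of the shared miRNAs (SD, n = 4) and HFD arrays 138 ± 23.0 (SD, n = 4). The second design detected 130 and 163 on its Control arrays and 184 on its HFD array. The difference in number of miRNAs detected per array, within array design, was 4.88 (2-sided exact permutation p = 0.690), and the 75th percentile of signal per array differed by 0.073 on the log2 scale (2-sided exact permutation p = 0.819). Both had the opposite sign on the first design alone, as without HFD 640, at -6 and -0.059, and without Control 635, at -0.6 and -0.075. HFD 653 stood apart, with 105 miRNAs detected and a spread of negative control signal of 38.2, against 6.38 to 7.53 on the other 7 arrays of its slide. Without HFD 653 the difference in detected miRNAs was 14.2 (2-sided exact permutation p = 0.171).

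No single miRNA passed the test in the islets of HFD daughters. Of the 152 miRNAs tested with limma, 0 passed an adjusted p of 0.05, the smallest adjusted p was 0.987, and 3 had an unadjusted p under 0.05, all 3 with higher values in HFD. Those were miR-150, a miRNA abundant in lymphocytes, miR-431, which belongs to the imprinted Dlk1-Meg3 cluster, and miR-296*. The median standard error over the 152 was 0.18 on the log2 scale. Of the 84 miRNAs detected on all 11 arrays and not held constant by the scaling, the 95% confidence interval excluded a 2-fold difference in both directions for 78 and a 1.5-fold difference for 63. These counts hold for the scaling used, and the intervals carry no uncertainty from the choice of scaling. In the first array design alone limma also called 0 miRNAs, with 2 at an unadjusted p under 0.05. The interaction between diet and array design gave 0 miRNAs after adjustment and 1 before, where the lone HFD array of the second design is assumed to vary like the other groups. That design alone allowed values only, and 79 of 152 miRNAs had the same sign in both designs.

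miR-150 had a log2 difference of 1.73 ± 0.61 (SE), a 3.32-fold higher fitted level in HFD with a 95% interval of 0.36 to 3.1 on the log2 scale. Its first-design values were 5.70 ± 1.74 in HFD (SD, n = 4) and 3.63 ± 0.14 in Control (SD, n = 4), and on the second design the HFD array read 4.73 against a Control mean of 4.0. All 5 HFD arrays lay above each Control array of their own design, which chance gives in 0.952% of cases per miRNA in either direction and which held for 1 of the 152 miRNAs, with 1.45 expected by chance. The 2-sided exact permutation p was 0.0048, the smallest that 210 within-design splits can give, and its adjusted value over 152 miRNAs was 0.724. miR-150 was detected on 3 Control and 4 HFD arrays, and the first-design Control values lie between the floor of 3.49 and 3.79. The difference was 0.24 with the RMA-like summary, 0.29 with normexp, 0.54 in the deposited tables, 1.11 as the median over probes, 1.09 with array weights, 1.15 with a higher floor and 0.71 without both HFD 603 and HFD 653. With no scaling between arrays limma called it, with an adjusted p of 0.00062, and the next smallest over its 31 alternatives was 0.521 and the highest 1.

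**Figure D1:**
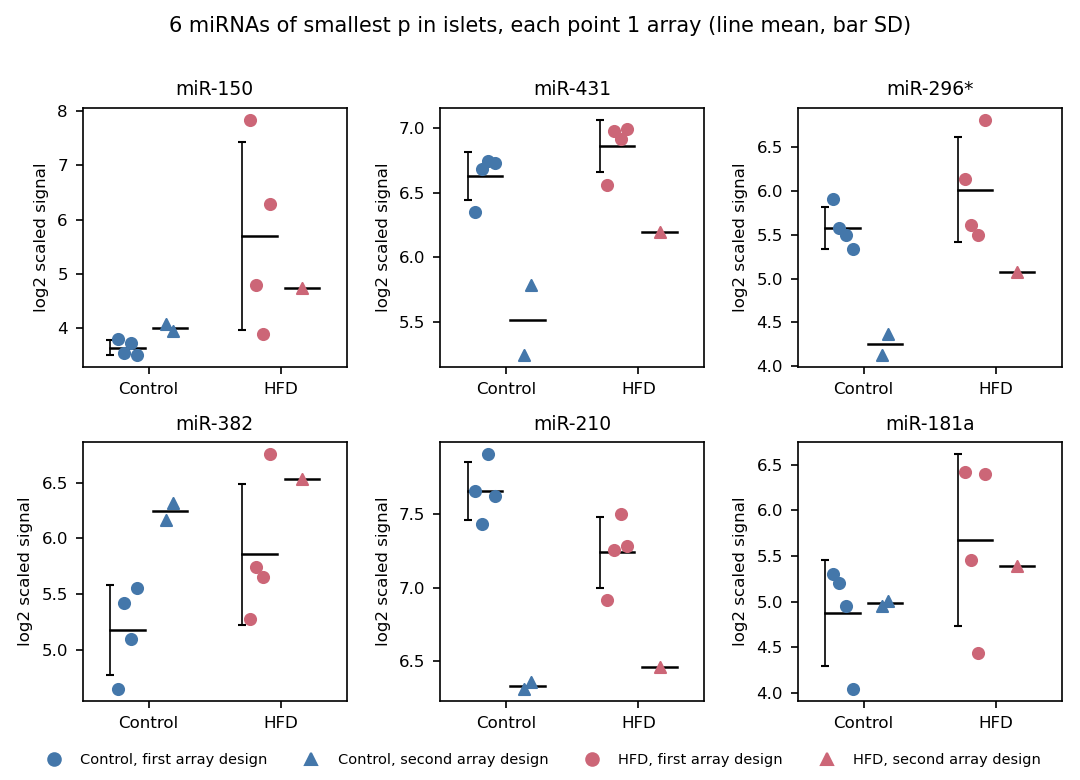
Log2 scaled signal (vertical axis) on each array for the 6 miRNAs of smallest p, by group (horizontal axis); circles are arrays of the first design and triangles of the second, horizontal lines are means and bars are SDs of the 4 first-design arrays. The miR-150 values of HFD lie above those of Control within each design and run from 3.88 to 7.84 on the first.

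The next miRNAs by p did not pass either. The differences were 0.35 ± 0.15 for miR-431 and 0.53 ± 0.23 for miR-296* (SE), and both depend on processing. miR-431 had 0.12 when scaled by the 75th percentile over all shared miRNAs or with normexp, 0.17 under quantile normalisation, 0.19 with median scaling, 0.15 in the deposited tables and 0.056 with the RMA-like summary, against 0.59 with the software's total signal. miR-296* had -0.0059 when outlier spots were kept, 0.12 under quantile normalisation, 0.094 with normexp, 0.025 with the RMA-like summary, 0.22 in the deposited tables, 0.31 with the first of these scalings and 0.35 without HFD 653. miR-382, miR-341, miR-433 and miR-369-5p, all of the Dlk1-Meg3 cluster, had 0.58, 0.63, 0.43 and 0.24. Without HFD 653 miR-382, miR-341 and miR-369-5p had 0.35, 0.28 and 0.13, without Control 602 miR-433 had 0.25, and with the RMA-like summary miR-433 and miR-369-5p had -0.021 and -0.013. miR-210, which hypoxia induces in many cells, read -0.28 ± 0.14 (SE), with -0.42 in the first design, 0.13 in the second and -0.19 without HFD 603. miR-181a and miR-345-5p read 0.70 and 0.71, miR-383 and miR-340-3p 0.41 and 0.46, and miR-342-3p and miR-325-5p 0.22 and 0.20. With the RMA-like summary miR-181a had 0.073, and in the deposited tables, where its HFD 640 cell is altered as described below, 2.23. Without HFD 653 miR-345-5p had 0.33 and miR-340-3p 0.14, without Control 602 miR-342-3p had 0.12, without HFD 640 miR-325-5p had 0.11, and with the RMA-like summary miR-383 had -0.026. Of the 4 first-design probes of miR-325-5p, which lay at the floor on 5 of those 8 arrays, 2 read lower in HFD and 0 higher. let-7e was the only other of the first 15 below 0, at -0.17 ± 0.12 (SE), or -0.11 without HFD 603.

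The general level of the differences depends on how arrays were scaled. Over all 152 miRNAs 108 were above 0 and 44 below, with a median of 0.066. Scaling by the 75th percentile over all shared miRNAs moved that median by -0.21, scaling by the median by -0.15 and quantile normalisation by -0.13. Under those 3 settings 36, 49 and 48 miRNAs were above 0. With unscaled arrays it moved by 0.089, and 134 were above 0. Counts of list members above and below 0 therefore hold for the scaling used and not for each of these.

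The islets' own endocrine miRNAs did not differ detectably. Of the islet endocrine-enriched list, 22 members were tested, 15 read higher and 7 lower in HFD, and the mean difference was 0.037 ± 0.14 (SE). miR-375, which beta cells hold in large amounts and which restrains insulin secretion, was 12.22 ± 0.24 in Control and 12.19 ± 0.16 in HFD on the first design (SD, n = 4), a fitted difference of -0.031 ± 0.12 (SE) with a 95% interval of -0.30 to 0.24. miR-7a, another endocrine miRNA, differed by 0.050 ± 0.11 (SE), miR-487b by 0.23 and miR-204 by 0.22. Single arrays weighed on miR-487b and miR-204. For miR-487b Control 602 read 4.35, against 5.04 to 5.21 on the other first-design Control arrays. For miR-204 HFD 653 read 8.36, against 7.49 to 7.67 on the other first-design HFD arrays. miR-184 was not detected on any array. camera's direction for the list was down relative to the other miRNAs although its mean was above 0 (adjusted p = 0.728, and 0.910 with an estimated correlation). The list mean was -0.0035 within the first design and 0.16 within the second, and -0.050 without Control 602.

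The let-7 family, which holds down growth-related transcripts, was called lower relative to the other miRNAs by camera with its preset correlation of 0.01 (adjusted p = 0.042). The correlation estimated among its members was 0.47, far above the preset, and with that estimate the call was lost (camera adjusted p = 0.910). Of 8 tested members, 6 read lower and 2 higher in HFD. The mean was -0.044 ± 0.056 (SE), or 0.028 with unscaled arrays, -0.27 when scaled by the 75th percentile over all shared miRNAs, -0.20 with median scaling and -0.013 without Control 602, with a shift of -0.17 against the other miRNAs that was -0.15 within the first design and -0.22 within the second. let-7e differed by -0.17, let-7c by -0.076 ± 0.093 and let-7i by 0.10 ± 0.096 (SE). On each second-design array the scaling set let-7i or let-7d to a fixed value. This constrains their differences on that design, which were 0.018 and 0.0086. fry, which tests the members against no change, gave an adjusted p of 0.902. The exact permutation p of the shift was 0.081, and under quantile normalisation the shift was 0.026. The call was also lost on leaving out any of Control 602 (shift -0.12), Control 652 (-0.15), HFD 603 (-0.15), HFD 607 (-0.13), HFD 644 (-0.19) and HFD 640 (-0.15). Cross-hybridisation between family members, whose sequences are alike, was not tested.

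The maternally expressed miRNAs of the imprinted Dlk1-Meg3 locus read higher in HFD without passing the test. Of 20 tested members, all of which lie between Dlk1 and Dio3 in the GRCr8 gene table, 16 were above 0 and 4 below, with a mean of 0.19 ± 0.14 (SE), which was -0.017 when scaled by the 75th percentile over all shared miRNAs, -0.058 under quantile normalisation and 0.088 without Control 602. camera gave an adjusted p of 0.060 for a shift of 0.088 against the other miRNAs, and 0.910 with an estimated correlation. The shift was 0.050 within the first design and 0.20 within the second. Without Control 602 it was -0.011, while it passed without Control 613 (0.13), Control 639 (0.15) or HFD 603 (0.18), and its adjusted p ran from 8.9e-06 to 0.910 over 33 alternatives.

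Markers of other cell types that an islet preparation can hold passed no test. The leukocyte list had 5 tested members with a mean of 0.34, or 0.18 without HFD 603, and a median of 0.010, with 1.73 for miR-150, and miR-223, miR-146a and miR-146b read 0.14, -0.082 and -0.11. The endothelial list had 3 tested members, all 3 higher in HFD, with 0.10 for miR-126, 0.26 for miR-10a-5p and a mean of 0.17. That mean was 0.26 within the first design and -0.089 within the second, and 0.023 without HFD 603. HFD 603 had the highest first-design values of miR-126 (9.40) and miR-10a-5p (7.63). The fibroblast and smooth muscle list had 8 of 9 higher, with 0.41 for miR-10b, 0.26 for miR-100 and a mean of 0.13, which was 0.052 without Control 639 and 0.061 without HFD 603. The neuronal list had 4 of 6 higher, with 0.42 for miR-212, 0.14 for miR-128 and a mean of 0.077, which was 0.0084 without HFD 640. The red blood cell list had 2 tested members, miR-15b at 0.086 and miR-16 at 0.0029, while miR-451, rich in red cells, was detected on the 3 second-design arrays alone. Camera adjusted p values were 0.992 for leukocyte, 0.728 for endothelial and for fibroblast and smooth muscle, 0.992 for neuronal and 0.825 for red blood cell. Of the exocrine list, miR-216a, a miRNA of enzyme-secreting acinar cells, was the 1 member tested. It differed by 0.68 ± 0.84 (SE) between groups, and spread over 31.8-fold among the 8 first-design arrays, from 23.0 on Control 639 to 731.8 on HFD 603 in scaled signal. miR-217 was detected on 1 Control array of the first design and on all 3 of the second. The muscle and liver lists had 0 members tested, and miR-122, a liver miRNA, was not detected on any array.

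**Figure D2:**
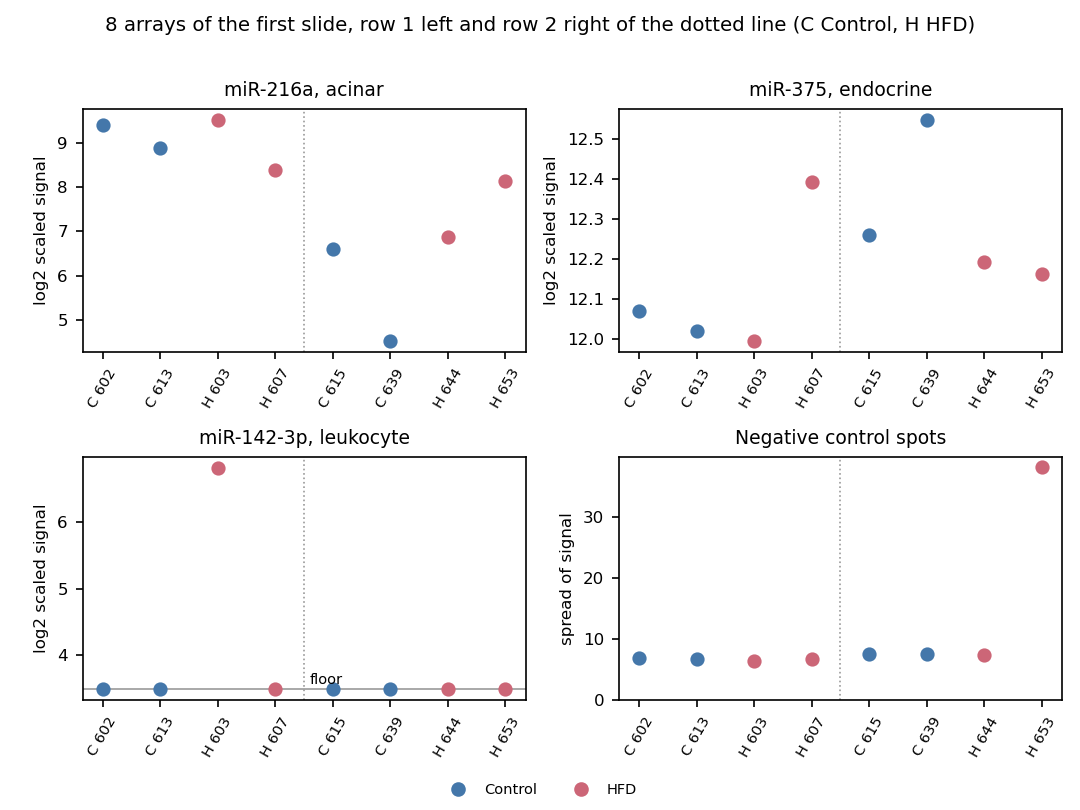
Log2 scaled signal of miR-216a, miR-375 and miR-142-3p, and the spread of negative control signal in linear units (vertical axes), on the 8 arrays of the first slide (horizontal axes), with row 1 of the slide left and row 2 right of the dotted line. miR-216a runs from 4.53 on Control 639 to 9.52 on HFD 603, miR-142-3p is above the floor of 3.49 on HFD 603 alone, and the negative control spread reaches 38.2 on HFD 653.

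The remaining lists were also not called. The miR-200 family, which marks epithelial cells, had a mean of 0.013, with 0.0083 for miR-200c, 0.056 for miR-141, 0.055 for miR-429 and -0.054 for miR-200a (camera adjusted p = 0.728). The miR-29 family, which targets collagen mRNAs, had 0.093 for miR-29a and 0.073 for miR-29b, a mean of 0.072 and a camera adjusted p of 0.754. The miR-30 family had a mean of -0.0073, with 0.094 for miR-30c and 0.081 for miR-30a (camera adjusted p = 0.728). The miR-17-92 clusters had a mean of 0.039, with 0.074 for miR-93 and 0.15 for miR-92a, and the miR-23, miR-24 and miR-27 clusters 0.076, with 0.13 for miR-23a and 0.15 for miR-27a (camera adjusted p = 0.754 for both). The list of miRNAs linked to diabetic or glucose-exposed islets had 14 of 17 members higher and a mean of 0.11 ± 0.056 (SE; camera adjusted p = 0.806, exact permutation p of the mean 0.076). The mean over all 152 miRNAs was also 0.11, and the shift of this list against the others was 0.0027 (exact permutation p = 0.962). The beta-cell stress and hypoxia list had 3 of 5 higher, with 0.23 for miR-34a, and a mean of 0.020 (camera adjusted p = 0.728). The means of the miR-200, miR-30, miR-17-92 and beta-cell stress lists had the other sign on leaving out some single arrays, and without Control 602 the mean was 0.0069 for the miR-29 family and 0.017 for the miR-23, miR-24 and miR-27 clusters. Mean and camera direction differed in sign for the red blood cell, neuronal, miR-200, miR-17-92 and beta-cell stress lists as well. The let-7 call was the 1 call of camera over 15 lists, and with an estimated correlation there were 0 (smallest adjusted p = 0.910). Against no change, fry called 0 lists (smallest adjusted p = 0.902). Over the 15 lists tested, 0 members passed when adjusted over the list alone, as when adjusted over all 152.

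**Figure D3:**
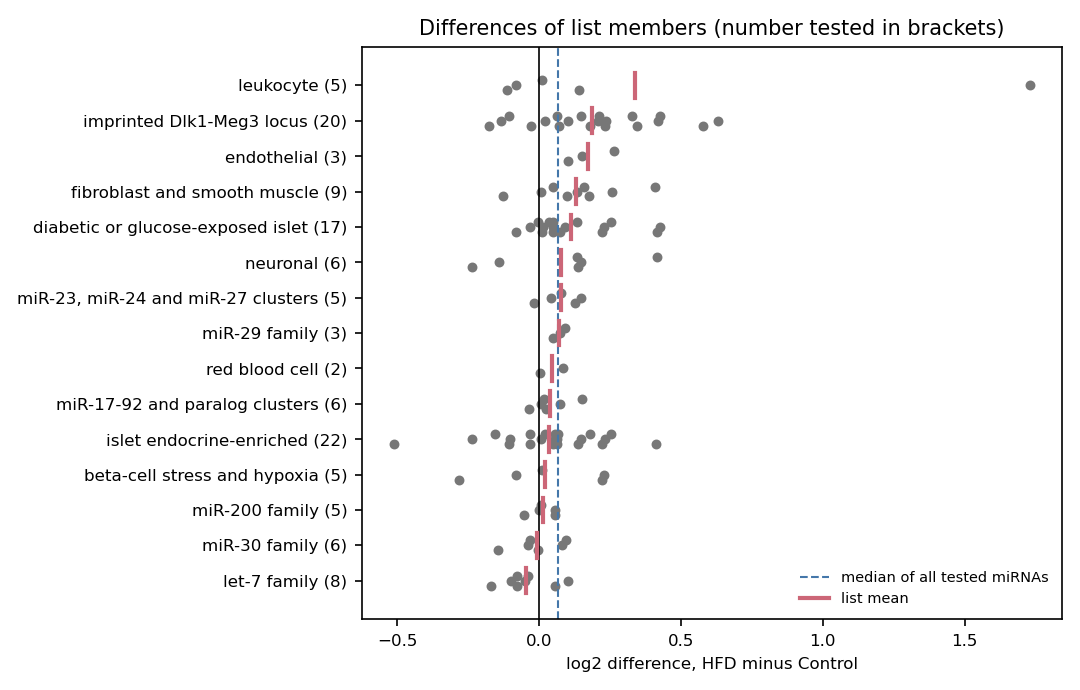
Log2 difference, HFD minus Control, of each tested member of 15 lists (grey points), with list means as red bars and the median of all 152 tested miRNAs, 0.066, as a dashed line. The leukocyte mean of 0.34 includes miR-150 at 1.73.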

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

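The tests of leukocytes, of a single probe, of acinar RNA, of slide position and of the diet for the miR-142-3p, miR-150 and miR-216a patterns were chosen after the values were seen. In groups of 4 on the first array design, 126 groups were checked for 1 array far from the others, and 12 met Dixon's criterion where chance gives about 6.3. The ratio of gap to range was 0.836 for miR-431 in Control (602 low), 0.838 for miR-340-3p in Control (602 low), 0.912 for miR-223 in Control (602 high) and 0.872 for miR-30c in Control (602 low). It was 0.934 for miR-200c in Control (615 high), 0.843 for miR-93 in Control (613 high), 0.881 for miR-10a-5p and 0.948 for the endothelial list in Control (639 low), and 1 for miR-325-5p in Control, where 639 read 3.74 and the others lie at the floor of 3.49. In HFD it was 0.887 for miR-383 and 0.883 for the Dlk1-Meg3 list mean (603 low, at 5.91 against 6.30 to 6.35), and 0.883 for miR-340-3p (653 high).

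A signal outside the tested miRNAs was miR-142-3p, made by blood-forming cells, at a scaled signal of 112.1 on HFD 603 against 3.57 to 8.58 on the 4 Control arrays of the slide. It was at least 9.95-fold above the other 7 arrays, taken at the floor since it was not detected there, although on the second design it was detected on all 3 arrays (log2 6.17 and 5.46 in Control and 6.42 in HFD), and miR-150 was also highest on HFD 603, at 7.84. Both miR-142-3p probes lay above the other arrays, the smaller distance being 7.41 SDs from their mean. A single cross-hybridising probe is thus argued against for miR-142-3p. An RNA that cross-hybridises to both of its probes would raise both and is not excluded by this. For miR-150, 1 probe read a scaled signal of 209.3 on HFD 603, 10.4 SDs above the mean of the other 7 arrays. Its other probe read 20.3, which is 2.83 SDs above, against at most 16.4 on those arrays. A single probe thus stays open as the source of the miR-150 value on HFD 603. A diet effect of the size seen on HFD 603, shared by the group, is argued against for miR-142-3p. Its mean on the other 3 HFD arrays was 5.84, inside the Control range. For miR-150 the diet stays open, since the lowest of those HFD arrays exceeded the highest Control array by 0.095, less than the Control SD of 0.14. Leukocytes in this 1 preparation may be the source. miR-142-5p, an untested member of that list, read 4.39 on HFD 603 and lay at the floor of 3.49 on the other 7 arrays of the slide. The other 4 tested members, miR-146a, miR-223, miR-21 and miR-146b, deviated on HFD 603 by 0.91, 0.23, 0.19 and -0.14, with a median of 0.21. Of these, miR-146a alone lay above all of the other 7 arrays. Of the 5 tested members 2 are also in another list. But lists of other cells were also highest on HFD 603. Their means were 8.26 for endothelial (others at most 7.81), 9.54 for red blood cell (9.19) and 7.49 for fibroblast and smooth muscle (7.41). The red blood cell list is miR-15b and miR-16 alone. miR-451 lay at the floor on all 8 arrays of the slide, so it cannot tell HFD 603 from the others. The miR-17-92 (7.03), diabetic or glucose-exposed islet (8.18) and beta-cell stress (7.55) lists were highest there too. Islet endocrine-enriched was not, at 7.66 (7.53 to 8.15). The leukocyte source thus stays open.

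The acinar miRNA miR-216a spread 29.5-fold among the 4 Control arrays alone, a log2 range of 4.88, so the diet is argued against as the source of that spread. It was higher on row 1 of the slide (9.04 ± 0.53, SD, n = 4) than on row 2 (6.53 ± 1.5, SD, n = 4), with an exact permutation p of 0.0286, the smallest that 70 splits can give, an adjusted p over all tested miRNAs of 0.256 by limma, and 2 arrays of each group per row. Array position stays open, since the row difference of -2.51 exceeded that of all other 151 tested miRNAs (99% range -0.91 to 0.72) but 22 of 152 had an unadjusted row p under 0.05 where chance gives 7.6. Row 1 held Control 602 and 613 and HFD 603 and 607, and row 2 held the higher sample numbers. Slide row can therefore not be told apart from the order of sample numbers. Acinar RNA carried into the preparations may be the source, and 1 miR-217 probe, picked after its values were seen, was compared with miR-216a (r = 0.56, exact permutation p = 0.154, adjusted 0.256; rho = 0.83, p = 0.0154, adjusted 0.038; r = 0.59 without the 2 farthest arrays, over 8 arrays and 5 relations). That probe is near background and read lowest on the noisy HFD 653, without which r was 0.93. Centred by row, a test added after the values were seen, r was -0.27 (exact permutation p = 0.580 over 576 orders within rows, adjusted 0.580; rho = 0.30, p = 0.559, adjusted 0.677; r = -0.24 without the 2 farthest arrays). Centring also removes any difference in acinar RNA between the rows, so it cannot weigh against acinar RNA that differs by row. This explanation stays open, and each row of 4 is too few for a correlation of its own.

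On the second array design, 10 miRNAs absent from the first were detected on HFD 640 and on neither Control array of that slide. HFD 640 had the highest number of detected miRNAs of the 3, 218 against 144 and 187, and 0 such miRNAs were detected on both Control arrays and not on HFD 640.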

How the results depend on the processing

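The alternatives without both HFD 653 and Control 635, without both HFD 603 and HFD 653, with slide row in the block, and with the deposited tables less 7 altered cells were chosen after seeing the data. The count of 0 changed miRNAs in limma held under 31 of 32 alternatives, with 3 in the values reported at an unadjusted p under 0.05. The exception left the arrays unscaled, and gave 1 changed miRNA, 1 higher in HFD, which was miR-150 with an adjusted p of 0.00062. Its next smallest adjusted p over 31 alternatives was 0.521 and its highest 1, with differences of 0.24 to 2.13. No paired analysis was possible because the 2 diet groups share no replicate numbers. Slide and scan coincided with array design, so a separate slide block was not run. All 100 of 100 splits of the arrays within array design had at least as many changed miRNAs as the real split, as a real count of 0 fixes in advance, so that count says nothing about chance, and the highest other split had 2. As many miRNAs at an unadjusted p under 0.05 as the real 3 came in 53 of the 100 splits, so chance cannot be excluded for those.

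For the let-7 list the call depended on the method. The shift against the other miRNAs was -0.17 with camera's preset correlation, and the same shift of -0.17 was not called with an estimated correlation (adjusted p = 0.910). The planned fry has no value for the shift, since it tests the members against no change (adjusted p = 0.902). The call was also lost with unscaled arrays (-0.18), the median over probes (-0.15), the RMA-like summary (-0.032), the deposited tables (-0.098), the first array design alone (-0.15), no block (-0.081), outlier spots kept (-0.17) and slide row in the block (-0.15). The deposited tables without the 7 altered cells kept the call (-0.12, camera adjusted p = 0.015). The adjusted p ranged from 3.3e-06 to 0.911 over 33 alternatives, 17 of which kept it under 0.05. The call was lost on leaving out Control 602 (-0.12), HFD 603 (-0.15), HFD 607 (-0.13), HFD 644 (-0.19), Control 652 (-0.15) or HFD 640 (-0.15), 6 of 11 arrays. Camera does not use limma's trend and robust variance, so for lists that alternative repeats the reported values by construction. Leaving out HFD 640 gives the same differences as the first design alone, so those alternatives are not independent. For the Dlk1-Meg3 list, past no threshold as reported, 10 of 33 alternatives gave an adjusted p under 0.05. Among them were scaling by the median (0.089), the deposited tables without 7 cells (0.090), no filter (0.050), detection on all arrays (0.15), quality weights (0.053), the higher floor (0.10) and leaving out both HFD 603 and HFD 653 (0.20). So did leaving out Control 613 (0.13), Control 639 (0.15) or HFD 603 (0.18), while without Control 602 the shift was -0.011. Leaving out both HFD 603 and HFD 653 also brought the miR-17-92 list past the threshold (-0.21). Camera called at least 1 list in 65 of the 100 splits, at most 4 in any other split against 1 in the real one. A camera p for let-7 as small as the real one came in 17 of the 100. Chance can therefore not be excluded for the let-7 call either. The interaction count was 2 with the deposited tables and 19 with no filter. Of those 19, 18 are miRNAs at the floor on all arrays of the first design.

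Of 1453 values of the 46 named miRNAs under 32 alternatives, 148 had the opposite sign to the reported value, and 10 miRNAs never changed sign. The cause was not tested, except that another factor per array moves all miRNAs above the floor alike by construction, and for altered cells of the deposited tables. For lists, the values compared are shifts of the list against the other miRNAs, which can have another sign than the list mean given above. As reported, those shifts were -0.088 for the islet endocrine-enriched list, 0.061 for the endothelial list, -0.068 for the red blood cell list, 0.23 for the leukocyte list, 0.019 for the fibroblast and smooth muscle list, -0.036 for the neuronal list and -0.17 for the let-7 family list. They were also -0.10 for the miR-200 family list, -0.041 for the miR-29 family list, -0.12 for the miR-30 family list, -0.076 for the miR-17-92 and paralog clusters list, -0.037 for the list of the miR-23, miR-24 and miR-27 clusters, 0.088 for the imprinted Dlk1-Meg3 locus list and 0.0027 for the diabetic or glucose-exposed islet list. Scaling by the 75th percentile over all shared miRNAs gave -0.0031 for miR-342-3p, -0.17 for miR-7a, -0.22 for miR-200c, -0.17 for miR-141, -0.12 for miR-126, -0.084 for miR-223 and -0.14 for miR-15b. It also gave -0.22 for miR-16, -0.087 for miR-128, -0.12 for let-7i, -0.17 for miR-429, -0.13 for miR-29a, -0.15 for miR-29b and -0.13 for miR-30c. Further values were -0.14 for miR-30a, -0.010 for miR-93, -0.074 for miR-92a, -0.10 for miR-23a, -0.075 for miR-27a and -0.0034 for miR-204, and a list shift of -0.0042 for the diabetic or glucose-exposed islet list. Quantile normalisation within array design gave -0.00079 for miR-433, -0.0052 for miR-383, -0.017 for miR-200c, -0.37 for miR-223, -0.10 for miR-34a, -0.19 for miR-487b, -0.0036 for miR-15b, -0.079 for miR-16 and -0.0049 for miR-10b. It also gave -0.051 for miR-100, -0.27 for miR-128, -0.0020 for miR-429, -0.047 for miR-30c, -0.077 for miR-30a, -0.061 for miR-93, -0.18 for miR-92a and -0.039 for miR-27a, and list shifts of 0.052 for the red blood cell list, 0.026 for the let-7 family list, 0.079 for the miR-200 family list, 0.16 for the miR-29 family list and 0.10 for the list of the miR-23, miR-24 and miR-27 clusters. Leaving the arrays unscaled gave 0.042 for miR-375, 0.088 for miR-146a and 0.019 for miR-200a. Scaling by the median gave -0.10 for miR-7a, -0.14 for miR-200c, -0.10 for miR-141, -0.052 for miR-126, -0.012 for miR-223, -0.067 for miR-15b, -0.15 for miR-16, -0.015 for miR-128 and -0.051 for let-7i. It also gave -0.10 for miR-429, -0.060 for miR-29a, -0.079 for miR-29b, -0.059 for miR-30c, -0.072 for miR-30a, -0.0018 for miR-92a, -0.025 for miR-23a and -0.0034 for miR-27a, and a list shift of -0.0044 for the diabetic or glucose-exposed islet list. The normexp background correction gave -0.0036 for miR-200c, 0.027 for miR-146a, 0.024 for miR-146b and -0.00064 for miR-93, and list shifts of 0.026 for the neuronal list, 0.018 for the miR-29 family list and 0.021 for the list of the miR-23, miR-24 and miR-27 clusters. The software's total gene signal gave 0.13 for miR-146b, and list shifts of -0.0054 for the fibroblast and smooth muscle list and 0.027 for the neuronal list. The median over probes gave -0.012 for miR-15b, 0.062 for miR-146b and -0.066 for miR-93. The RMA-like summary gave -0.021 for miR-433, -0.026 for miR-383, -0.014 for miR-325-5p, -0.013 for miR-369-5p, -0.013 for miR-200c, -0.018 for miR-126, -0.061 for miR-223 and -0.013 for miR-487b. It also gave -0.0053 for miR-15b, -0.061 for miR-16, -0.044 for miR-128, -0.055 for miR-429, -0.041 for miR-30a, -0.015 for miR-93 and -0.032 for miR-92a, and list shifts of 0.033 for the neuronal list, 0.071 for the miR-29 family list and 0.048 for the list of the miR-23, miR-24 and miR-27 clusters. The deposited log2 tables gave 0.051 for miR-375, -0.24 for miR-126, 0.084 for miR-146a, 0.0048 for let-7c, 0.0051 for miR-146b, 0.046 for miR-200a, -0.054 for miR-93 and -0.62 for miR-27a, and list shifts of -0.14 for the endothelial list, -0.045 for the leukocyte list, 0.058 for the neuronal list and 0.019 for the miR-29 family list. Among these, miR-126 on Control 635 (12.23 in place of 8.91) and miR-27a on Control 652 (15.26 in place of 8.61) are altered cells. miR-126 is also a member of the endothelial list. The deposited tables without the 7 altered cells gave 0.051 for miR-375, 0.084 for miR-146a, 0.0048 for let-7c, 0.0051 for miR-146b, 0.046 for miR-200a and -0.054 for miR-93, and list shifts of -0.069 for the leukocyte list and 0.034 for the neuronal list. Testing all shared miRNAs gave a list shift of -0.019 for the diabetic or glucose-exposed islet list. Testing miRNAs detected on all arrays gave a list shift of 0.034 for the neuronal list. The first array design alone gave -0.045 for miR-200c, -0.044 for miR-141, -6 for the number of miRNAs detected per array and -0.059 for the 75th percentile of signal per array, and a list shift of -0.0050 for the diabetic or glucose-exposed islet list. A fit with no block gave -0.064 for miR-325-5p, -0.00053 for miR-7a, 0.040 for let-7c, -0.027 for miR-100, -0.11 for miR-30c, -0.023 for miR-30a, -0.094 for miR-93 and -0.084 for miR-23a, and list shifts of 0.039 for the red blood cell list, 0.023 for the neuronal list and 0.0096 for the miR-17-92 and paralog clusters list. Array quality weights gave 0.031 for miR-375, -0.014 for miR-223, 0.077 for miR-146a, 0.077 for miR-146b and -0.10 for miR-92a, and list shifts of -0.078 for the endothelial list and 0.086 for the neuronal list. Keeping outlier spots gave -0.0059 for miR-296*. A floor at the 5th percentile gave 0.089 for miR-146a. Leaving out both HFD 653 and Control 635 gave -0.032 for miR-200c, 0.31 for miR-146a, 0.031 for miR-146b and -0.016 for miR-429, and list shifts of 0.035 for the red blood cell list and 0.059 for the neuronal list. Leaving out both HFD 603 and HFD 653 gave 0.043 for miR-375, -0.21 for miR-223, -0.15 for miR-34a, 0.051 for miR-146a, -0.036 for miR-10a-5p, 0.13 for miR-146b, 0.0062 for miR-200a and -0.26 for miR-92a, and list shifts of 0.10 for the islet endocrine-enriched list, -0.20 for the endothelial list, -0.058 for the fibroblast and smooth muscle list, 0.14 for the neuronal list and 0.015 for the miR-30 family list. A block of array design and slide row gave -0.0062 for miR-200c. Leaving out 1 array at a time gave ranges of -0.079 to 0.048 for miR-375, -0.019 to 0.11 for miR-7a, -0.045 to 0.059 for miR-200c, -0.050 to 0.15 for miR-141 and -0.023 to 1.15 for miR-216a. The ranges were -0.079 to 0.30 for miR-223, -0.0088 to 0.42 for miR-34a, -0.28 to 0.21 for miR-146a, -0.11 to 0.23 for miR-15b and -0.036 to 0.054 for miR-16. Further ranges were -0.24 to 0.049 for miR-146b, -0.00073 to 0.11 for miR-429, -0.0052 to 0.12 for miR-29b, -0.025 to 0.17 for miR-30a and -0.10 to 0.32 for miR-92a. The shifts of lists against the other miRNAs then ranged over -0.089 to 0.18 for the endothelial list, -0.18 to 0.027 for the red blood cell list, -0.052 to 0.10 for the fibroblast and smooth muscle list and -0.10 to 0.057 for the neuronal list. Other list shifts then ranged over -0.21 to -0.12 for the let-7 family list, -0.092 to 4.4e-05 for the miR-29 family list, -0.011 to 0.18 for the imprinted Dlk1-Meg3 locus list and -0.019 to 0.049 for the diabetic or glucose-exposed islet list. Per array, leaving out 1 gave differences of -6 to 14.16 for the number of miRNAs detected per array and -0.075 to 0.17 for the 75th percentile of signal per array. List means, unlike those shifts, ran on leaving out 1 array over -0.050 to 0.10 for the islet endocrine-enriched list, 0.023 to 0.31 for the endothelial list, -0.072 to 0.14 for the red blood cell list, 0.18 to 0.45 for the leukocyte list and 0.052 to 0.23 for the fibroblast and smooth muscle list. Other list means then ran over 0.0084 to 0.17 for the neuronal list, -0.079 to -0.013 for the let-7 family list, -0.029 to 0.061 for the miR-200 family list, 0.0069 to 0.11 for the miR-29 family list and -0.13 to 0.074 for the miR-30 family list. The remaining means ran over -0.084 to 0.10 for the miR-17-92 and paralog clusters list, 0.017 to 0.12 for the list of the miR-23, miR-24 and miR-27 clusters, 0.088 to 0.27 for the imprinted Dlk1-Meg3 locus list, 0.088 to 0.16 for the diabetic or glucose-exposed islet list and -0.034 to 0.067 for the beta-cell stress and hypoxia list. Signal over background sets a limit on dim miRNAs such as miR-150, whose Control arrays lie near the floor.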

Other observations

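The second array design carries 337 miRNAs that the first lacks, and 14 of them were detected on all 3 of its arrays. Among these were miR-7a-2*, the passenger strand of an endocrine miRNA, and miR-1224, miR-129-1*, miR-129-2*, miR-652* and miR-216b-5p, named after their values were seen. Total signals on Control 635, Control 652 and HFD 640, in that order and unscaled, were 492.0, 478.8 and 762.6 for miR-1224 and 26.2, 79.1 and 85.0 for miR-7a-2*. The arrays differed in brightness, with 75th percentiles of 1018, 2362 and 2144 in the same order, so unscaled signals do not compare the groups. With 1 HFD array these signals are values with no test.

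miR-375, the endocrine miRNA, read lower where the acinar miR-216a was higher, over the 8 arrays of the first design (r = -0.82, exact permutation p = 0.012, adjusted 0.060; rho = -0.83, p = 0.0154, adjusted 0.038; 5 relations). Without the 2 arrays farthest from the median of miR-216a, r was -0.53, so the relation rests in part on those arrays, and each slide row of 4 is too few for its own value. Since rows differ in miR-216a, the relations were also computed after centring by row, with 576 orders within rows, a test chosen after the values were seen. For miR-375 this gave r = -0.82 (exact permutation p = 0.00868, adjusted 0.043), rho = -0.87 (p = 0.0174, adjusted 0.087) and r = -0.64 without the same 2 arrays. The islet endocrine-enriched list mean gave r = -0.66 (exact permutation p = 0.065, adjusted 0.163) and rho = -0.60 (p = 0.132, adjusted 0.220), and r = -0.69 without the same 2 arrays. The Dlk1-Meg3 mean gave r = -0.48 (exact permutation p = 0.231, adjusted 0.289), rho = -0.38 (p = 0.360, adjusted 0.450) and r = -0.73 without those 2, and the let-7 mean r = 0.013 (exact permutation p = 0.978, adjusted 0.978), rho = -0.19 (p = 0.665, adjusted 0.665) and r = 0.064 without those 2. Centred by row, these 3 gave r = -0.63 (exact permutation p = 0.073, adjusted 0.156), -0.20 (p = 0.378, adjusted 0.473) and 0.51 (p = 0.094, adjusted 0.156), rho = -0.67 (p = 0.118, adjusted 0.295), -0.21 (p = 0.677, adjusted 0.677) and 0.43 (p = 0.392, adjusted 0.654), and r = -0.94, -0.65 and 0.68 without those 2.

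In the authors' deposited log2 table of the second design, 7 of 549 detected cells differed by over 0.01 from log2 of the array's own signal. They were miR-126, miR-365 and miR-425 on Control 635, miR-136* and miR-27a on Control 652, and miR-181a and miR-342-3p on HFD 640, named after their values were seen. A candidate explanation, tested after the values were seen, is that the text 0.1, which the software writes for undetected miRNAs, was replaced by 1 before the log. All 7 changed cells equal log2 of the signal's text after that replacement (within 0.001), and 0 signals with that text were unchanged. For miR-27a on Control 652 a signal of 390.2 thus stands as a log2 of 15.26 in place of 8.61. In the deposited tables miR-27a differed by -0.62 between groups, against 0.15 in the scanner values, and no biological explanation was tested for these cells.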
